A study of Mus musculus with 4 samples.

How the data were processed

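The deposited tables held counts of unique molecules per gene and cell, made per the submitters' processing notes with Cell Ranger 3.0.2 and mm10, and Seurat 3.1.3.9002 was named there as well. The V(D)J tables held contigs with their UMIs, segment calls and productive calls as deposited. The gene annotation, the cell calling and the V(D)J reference were not given in the sources used here. Tables named genes by symbol, and 25166 of 31053 symbols matched the RefSeq table of GRCm38.p6, the same build as mm10. The 5 genes given with positions were chosen after the data were seen.

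The comparisons, the cell filter, the count minimums, the gene groups, the genes always reported and most alternatives were set before the data were examined. Cells with at least 500 genes and 1000 UMIs and at most 10% mitochondrial UMIs were kept, which left out 180 turnover and 190 autonomy barcodes. Scrublet called no doublet and none was removed, and removing the highest 4% of scores was tried as an alternative. Counts were scaled, log-transformed and centred per library, a step chosen after the data were seen because clusters otherwise split by library. Clusters came from 2000 variable genes, 30 components, 15 neighbours and Leiden clustering at a resolution of 1. TCR segment, sex, cell cycle, mitochondrial and ribosomal protein genes were left out of the variable genes. Clusters were named by markers with CPM thresholds set after the data were seen. The cluster with high Il2ra was not called DN3-like because Tcrg-C1 and Tcrg-C2 were among its leading genes, and genes were not compared in it because 8 autonomy cells were fewer than the 100 required.

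For each cell group, UMIs were summed per library and divided by the library total. Genes needed 200 UMIs over both libraries for all cells and 100 in a class. Ratios carry a conditional exact binomial interval, shares an exact interval, and ratios of shares a log-normal one. Where a library had no UMI, the fold was bounded with a floor of 3 counts in that library, which is no confidence limit, and the exact limits lay closer to 1. The text names the 12 highest and 12 lowest genes over all cells, the 6 highest and 6 lowest in each class, most of a fixed set of further genes, and up to the first 2 members by rank of each gene group outside the middle 95% of 10000 random lists, a display rule chosen after the data were seen. Members needed 20 UMIs. TMM factors came from edgeR. Phase was scored after thinning to 1000 UMIs.

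A chain was the nucleotide CDR3 with its V and J segment, and chain sharing was compared over 100 draws of 3000 cells. The Jensen-Shannon divergence was set against 100 random splits of each library. In the self-test, among simulated genes that kept the count minimum, folds of 2.4 and 4 were found in at least 92% of cases, a fold of 0.417 in 97.8%, 87.0%, 78.3% and 97.4% of cases in the 4 cell groups, and the intervals covered 95.1% to 95.7% of true values. The self-test was revised after its first run. Of 100 null gene lists per group, 7, 6, 3 and 5 lay outside the middle range. Simulated counts were drawn independently for each gene, so the interval coverage and these list counts do not extend to cells or genes that vary together. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, umap-learn 0.5.12, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.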

Results

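Wild-type mouse thymi were transplanted and taken after 28 days, and thymocytes sorted as DN3-DN4, immature single positive (ISP) and double positive (DP) cells were profiled with a droplet 5′ gene expression assay and a matched assay of rearranged T cell receptor (TCR) chains, V(D)J. In turnover, resident thymocytes are replaced by progenitors arriving from outside, and in autonomy the thymus sustains T cell production from its own cells. The labels did not describe the hosts or the number of animals. Cells with Xist and cells with Y-linked transcripts were both found in the autonomy library, which thus held cells of both sexes, from several animals or from donor and host, so autonomy values are averages over these cells. Each condition had 1 gene expression library and 1 V(D)J library, so no spread between animals could be measured and no test was made. All intervals are 95% and cover counting error only. They treat cells and UMIs as independent. However, 85.4% of autonomy and 4.26% of turnover cells with a productive TCR beta chain shared it with another cell. The intervals can therefore be too narrow, above all for the autonomy library. The turnover table held 4374 barcodes and 20163286 UMIs (unique molecules), and that of autonomy had 4587 barcodes and 16388810 UMIs. After filtering, 4194 turnover cells with a median of 2117 UMIs and 4397 autonomy cells with a median of 2433 UMIs were compared. The V(D)J tables held 12034 contigs with 177475 UMIs in turnover and 11821 contigs with 105865 UMIs in autonomy.

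The first question was which stages each library held. Small resting DP-like cells, which express Rag1 and both coreceptors, made up 65.3% of turnover cells (63.8 to 66.8) and 55.1% of autonomy cells (53.6 to 56.6), a ratio of 0.843 (0.815 to 0.873). Cycling ISP/DP-like cells were 16.1% of turnover cells (14.97 to 17.2) and 5.82% of autonomy cells (5.15 to 6.56). With the stricter filter they were 660 of 2314 turnover and 106 of 3361 autonomy cells. A cluster with high Il2ra, the interleukin-2 receptor chain that marks DN3 cells, held 122 turnover cells (2.91%, 2.42 to 3.46) and 8 autonomy cells (0.182%, 0.0786 to 0.358). Post-selection-like cells, with Itm2a and Cd69, were 13.7% in turnover and 11.9% in autonomy (574 and 523 cells). They were 430 and 455 cells at a resolution of 0.5 and 343 and 341 with the looser filter, so this difference depended on the settings. Mature single positive-like cells were 0.501% and 3.48% (21 and 153 cells). This class held 1 and 114 cells with cycle scores regressed out, 2 and 129 with no gene left out of the variable genes, 7 and 137 with the looser filter and 14 and 205 without centring. Clusters led by Dtx1 and other genes that differed between the libraries held 1.12% of turnover and 20.4% of autonomy cells. They passed the naming thresholds for small resting DP-like cells, set after the data were seen. Cd8a stood at 3409 and 3594 CPM in them and Rag1 at 1711 and 885 CPM. They were set apart because DN3 markers, Dtx1 with Ptcra or Dtx1 alone, were among their leading genes. Counted as small resting cells, they would turn the direction, with a higher share in autonomy. At a resolution of 0.5 such clusters held 620 turnover and 980 autonomy cells, against 47 and 895, and with genes 4-fold apart left out no such cluster was found. A further cluster carried macrophage transcripts together with DP transcripts (0.405% and 3.18%). The sort itself can set all of these shares. With clusters at a resolution of 0.5, or with genes 4-fold apart left out, the ratio for small resting cells was 0.997 or 0.983, so that difference depended on the clustering.

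Over all kept cells, the comparison asked which genes differed between the conditions. Dtx1, which encodes a ubiquitin ligase induced by Notch, was 68.0-fold higher in the autonomy library (53.9 to 87.1), at 245 against 3.60 counts scaled to a common library total (CPM). Heyl, a transcriptional effector of Notch, had 1 turnover and 102 autonomy UMIs, a ratio of 126 (22.1 to 5015). Ptcra, the invariant chain of the pre-TCR, was 3.50-fold higher (3.33 to 3.68), Notch1 2.81-fold (2.63 to 2.99) and Il2ra 2.19-fold (2.03 to 2.36). Hoxa7, a homeobox gene, was lower in autonomy at 0.0170-fold (0.00349 to 0.0505), from 217 and 3 UMIs. On mm10 (GRCm38), Dtx1 lies on chromosome 5 from 120680203 to 120711867, Notch1 on chromosome 2 from 26457902 to 26503822, Il2ra on chromosome 2 from 11642792 to 11693194, Ptcra on chromosome 17 from 46755663 to 46763712 and Hoxa7 on chromosome 6 from 52215623 to 52218573, and all are annotated as protein-coding.

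Exoc3l4 and Lypd1 had no turnover UMI and were at least 106-fold and 97.4-fold higher in autonomy, against a floor of 3 counts in the library. Ly6c2, a surface protein of some mature T cells, had 1 and 438 UMIs, a ratio of 540 (96.4 to 21378). Rpl39l had 1 and 250 UMIs (ratio 308, 54.8 to 12222), and H2-T3, a nonclassical MHC gene, 3 and 252 UMIs (ratio 104, 35.0 to 506). S1pr1, the receptor that guides mature T cells out of the thymus, was 59.2-fold higher and Klf2, a transcription factor that induces it, 42.3-fold. Ifit3 was 53.5-fold higher, Ifi213 40.1-fold, Arhgef10l 39.3-fold and Cpsf4l 31.5-fold. Among genes lower in autonomy were Ifitm2 (0.0631-fold), Bmyc (0.177-fold), Dnph1 (0.199-fold), Pdk2 (0.216-fold), the glutathione transferase genes Gstm1 (0.220-fold) and Gsto1 (0.2495-fold), Ybx3 (0.251-fold), the linker histone gene H1f0 (0.267-fold), the delta chain constant gene Trdc (0.276-fold), Tctex1d2 (0.276-fold) and Myl10 (0.291-fold). Several of these genes led clusters: Exoc3l4, Arhgef10l, Lypd1 and Dtx1 the Dtx1-led clusters (in the one led by Lypd1, 110 of 154 autonomy cells carried the same pair of TRB chains), S1pr1 and Klf2 the mature cluster, and Ifitm2 and Myl10 the Il2ra-high cluster. Without the mature and the macrophage-transcript clusters, a choice made after the data were seen, Ly6c2 was 8.38-fold higher, Klf2 12.01-fold, Ifit3 4.89-fold and Ifi213 13.3-fold, and Dtx1 stayed at 70.2-fold. S1pr1 then had no turnover UMI and so no fold, and 237 of its 240 autonomy UMIs lay in the mature cluster. With each cell thinned to 1000 UMIs, Dtx1 was 175-fold higher, Arhgef10l 61.4-fold, Notch1 5.12-fold and Il2ra 3.83-fold, but Ifit3 was 31.5-fold higher, Ifi213 20.98-fold, Klf2 20.5-fold and S1pr1 7.63-fold. Among the lower genes, Ifitm2 was then at 0.108-fold, Pdk2 at 0.0917-fold, Ybx3 at 0.413-fold, Gsto1 at 0.452-fold, Dnph1 at 0.459-fold, Myl10 at 0.4685-fold and Tctex1d2 at 0.636-fold.

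Of 8991 genes with enough counts, 1224 were at least 2-fold higher and 208 at least 2-fold lower in the autonomy library. The median gene stood 0.29 higher on the log2 scale, and cycling cells gave 11642172 of the 19996754 turnover UMIs and 4170241 of the 16219199 autonomy UMIs. On TMM factors, which take out that shift, 621 genes were higher and 438 lower. With thinned cells, 507 genes were at least 2-fold apart, and with 5 times the count minimum 649. Among other genes chosen beforehand, Lyl1 was 6.99-fold higher, Bcl2 2.64-fold, Hes1 1.78-fold (2.98-fold in thinned cells), Cd4 1.60-fold, Rag2 1.49-fold and Rag1 1.47-fold. Kit was at 0.487-fold, Mki67 at 0.398-fold, Trbc1 at 0.525-fold, Dntt at 0.773-fold, Myc at 0.799-fold and Trbc2 at 0.806-fold. Bcl11b (1.11-fold), Cd8a (1.18-fold), Cd8b1 (1.08-fold), Trac (1.13-fold) and Cd3e (1.19-fold) were near equal, and Il7r (1.38-fold) was at 0.864-fold in thinned cells and 0.635-fold without the mature and the macrophage-transcript clusters. In the cells of both libraries that had Y-linked and no Xist transcripts, a setting added after the data were seen, Trbc1 was at 1.05-fold, Kit at 0.866-fold, Pdk2 at 0.128-fold, Gstm1 at 0.114-fold and Hoxa7 at 0.0671-fold.

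Gene groups fixed beforehand were compared with random lists of matched expression, and each median is given on the log2 scale relative to those lists. Every 1 of 17 measured interferon response genes was at least 1.5-fold higher in autonomy (2.13), including Ifit3 and Ifi27l2a (25.5-fold). All 9 macrophage and granulocyte genes (3.16), with C1qc at 22.8-fold and Tyrobp at 22.5-fold, and all 7 dendritic cell genes (2.51), with H2-Eb1 at 10.1-fold and Cd74 at 7.99-fold, were higher, as was the macrophage-transcript cluster. Of 12 innate lymphoid and NKT genes 10 were higher (2.67), led by Klrd1 (31.8-fold), and of 12 MHC class I genes 10 were higher (1.25), with H2-D1 at 3.87-fold and H2-K1 at 3.69-fold. Without the mature and the macrophage-transcript clusters, H2-K1 was at 1.21-fold, Tyrobp 3.39-fold, C1qc 11.6-fold, Cd74 4.73-fold and Ifi27l2a 12.2-fold, Klrd1 had no turnover UMI and so no fold, and the innate median was 1.46. With thinned cells Tyrobp was at 62.95-fold, C1qc 11.3-fold, H2-Eb1 6.17-fold, Cd74 5.05-fold and Ifi27l2a 12.3-fold. In cells with Y-linked transcripts only, C1qc was at 38.6-fold, H2-Eb1 at 26.8-fold and Cd74 at 16.2-fold. Of 12 Notch targets and receptors, 9 were at least 1.5-fold higher and 2 lower (1.38).

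Groups tied to T cell signalling and maturation were also higher in autonomy. Of 16 TCR response genes 12 were higher (0.75), such as Nfil3 (5.68-fold) and Dusp2 (4.77-fold), and of 15 interleukin-7 receptor and STAT5 genes 11 (0.70), such as Socs3 (22.5-fold), a feedback inhibitor of cytokine signalling, and Jak3 (3.89-fold). Of 14 commitment factors 11 were higher (0.72; Tcf3 3.92-fold, Runx3 3.25-fold), of 13 quiescence genes 8 were higher and 1 lower (0.68; Foxo1 9.84-fold), and of 14 mature thymocyte genes 10 were higher (0.67). DP stage genes (8 of 16 higher, 0.52; Ets2 3.08-fold, Cd2 2.23-fold), TCR components (7 of 16, 0.43; Fyn 2.66-fold), immediate early and heat shock genes (6 of 12 higher and 2 lower, 0.58; Jund 4.79-fold, Fos 3.96-fold) and glucocorticoid response genes (6 of 10 higher and 1 lower, 0.51; Dusp1 2.66-fold, Ddit4 2.25-fold) followed by their medians. Apoptosis regulators (10 of 17 higher and 1 lower, 0.49; Bcl2a1b 3.21-fold) and p53 targets (11 of 16 higher and 1 lower, 0.41) were higher too. Bbc3, a proapoptotic p53 target, was 3.89-fold higher, while Cdkn1a, the p21 inhibitor, was at 0.222-fold. With thinned cells Jak3 was at 2.53-fold, Fyn at 1.70-fold, Bcl2a1b at 1.53-fold, Cd2 at 1.37-fold and Cdkn1a at 0.106-fold, and in cells with Y-linked transcripts only Bcl2a1b was at 12.5-fold and Fos at 8.01-fold.

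Cell cycle groups were lower in autonomy, as was the share of cycling cells. Of 52 G2/M genes 41 were at least 1.5-fold lower (-1.31; Ttk 0.303-fold, or 0.0477-fold with thinned cells, Cenpf 0.316-fold), and of 42 S phase genes 24 (-0.92; Rad51ap1 0.416-fold, Tipin 0.452-fold). Cytosolic ribosomal protein genes (10 of 20 lower, -0.44; Rps12 0.575-fold, Rpl3 0.575-fold), cholesterol synthesis genes (5 of 14 lower and 2 higher, -0.52; Sqle 0.511-fold) and glycolysis genes (5 of 16 lower and 3 higher, -0.35) were lower by their medians. Within glycolysis, Tpi1 was at 0.348-fold and the transporter gene Slc2a3 3.18-fold higher. Early progenitor factors went both ways, with 3 of 7 higher and 4 lower (-1.34), and Zfpm1 was 2.80-fold higher. The sex check list stood at -1.30, with Xist at least 2436-fold higher from 0 and 5927 UMIs and Ddx3y (0.513-fold), Eif2s3y (0.295-fold), Kdm5d (0.494-fold) and Uty (0.430-fold) lower. Medians of MYC-linked ribosome biogenesis (-0.32), hypoxia (-0.30), nuclear oxidative phosphorylation (-0.27), stroma (-0.19), chromatin (-0.03), B cell (-0.02), mitochondrially encoded (0.02), unfolded protein (0.08), gamma-delta (0.20) and V(D)J recombination (0.20) genes lay within the middle 95% of random lists. No erythroid gene had enough counts.

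Small resting DP-like cells were compared to ask which differences were found within a single named stage, although the clusters of this class still differed in size between the libraries. Dtx1 was 287-fold higher in autonomy (123 to 885), at 258 against 0.901 CPM, and was also present at 134 CPM in autonomy mature single positive-like cells. Il2ra was 8.63-fold higher (6.87 to 10.98), Notch1 5.95-fold (4.98 to 7.16) and Ptcra 4.25-fold (3.84 to 4.71), although all are usually low at this stage. Trbc1 was at 0.425-fold (0.408 to 0.442) and Trbc2 at 0.676-fold, and Dntt, which adds nucleotides to TCR junctions, at 0.672-fold. Cd4 (1.01-fold) and Rag1 (0.902-fold) were near equal. Hes1 had 0 turnover and 15 autonomy UMIs, at least 4.71-fold higher against the floor (exact lower limit 3.38), Bcl2 was 2.13-fold higher and Lyl1 4.24-fold. Rag2 (1.10-fold), Bcl11b (0.976-fold), Cd3e (0.922-fold), Cd8a (0.855-fold), Trac (0.809-fold) and Cd8b1 (0.731-fold) differed less. Myc (0.778-fold) was at 0.200-fold with the stricter filter, 0.514-fold at a resolution of 0.5 and 1.24-fold with genes 4-fold apart left out, Trdc was at 0.496-fold, Il7r had no UMI and Kit 3 and 1.

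Of 8074 genes in these cells, 664 were at least 2-fold higher and 69 lower, or 435 and 115 on TMM factors, and the median gene stood 0.14 higher (log2). With 5 times the count minimum, 261 genes were apart. Rpl39l (1 and 121 UMIs, ratio 114, 20.1 to 4535), Cpsf4l (2 and 196 UMIs, ratio 92.3, 25.2 to 767), Mzb1 (2 and 158 UMIs, ratio 74.4, 20.2 to 619), Foxb1 (17.3-fold) and Crmp1 (14.9-fold) were highest after Dtx1. Faah (0.149-fold), Tpi1 (0.153-fold), Pdk2 (0.154-fold), Gstm1 (0.157-fold), Tet2 (0.168-fold) and Car2 (0.202-fold) were lowest, and under the stricter cell filter Faah was at 0.0381-fold, Car2 at 0.477-fold, Dtx1 at 141-fold, Foxb1 at 70.7-fold, Gstm1 at 0.277-fold, Mzb1 at 47.8-fold, Lyl1 at 2.03-fold, Runx3 at 1.89-fold, Trdc at 0.247-fold and Notch1 at 2.69-fold. In cells with Y-linked transcripts only, Trbc1 was at 0.767-fold, Pdk2 at 0.0261-fold, Crmp1 at 29.7-fold, Runx3 at 7.52-fold and Ifi27l2a at 6.61-fold. Mzb1 was at 160-fold at a resolution of 2.0 and Cpsf4l at 180-fold with the highest doublet scores removed. Lyl1 was at 9.16-fold with cycle scores regressed out and 1.90-fold with the looser filter. Of 8 Notch genes 5 were higher and none lower (2.16), and all 14 interferon genes were higher (2.14; Ifi27l2a 10.9-fold, Ifit1 10.8-fold), and a cluster of this class led by such genes held 43 turnover and 235 autonomy cells. MHC class I (8 of 10, 0.88; H2-K1 3.27-fold, H2-D1 2.61-fold), dendritic cell (3 of 3, 2.02; Bst2 2.61-fold), immediate early (9 of 11, 0.83; Jun 5.91-fold, Jund 3.78-fold) and interleukin-7 receptor and STAT5 genes (9 of 12, 0.77; Socs3 13.1-fold, Socs1 2.17-fold) were higher. T commitment (7 of 14, 0.58; Tcf3 3.89-fold, Runx3 3.60-fold), p53 (7 of 15, 0.45; Bbc3 2.51-fold, Zmat3 1.97-fold) and quiescence genes (6 of 12, 0.42; Foxo1 7.20-fold, Btg1 3.16-fold) were higher by their medians. Ribosomal protein genes (8 of 20 lower, -0.45; Rpl32 0.605-fold, Rpl3 0.623-fold) and oxidative phosphorylation genes (1 of 20 lower, -0.20; Uqcrh 0.597-fold, Cox4i1 0.780-fold) were lower by their medians, and the sex check list stood at -1.63. DP stage genes (2 of 15 higher, 0.10), TCR components (6 of 16, 0.15) and TCR response genes (5 of 12 higher and 1 lower, 0.17), all higher over all cells, lay within the middle 95% of random lists here.

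Cycling ISP/DP-like cells, which had the highest counts per cell with medians of 15572 and 14151 UMIs, differed in many of the same groups. Dtx1 was 45.7-fold higher in autonomy (32.9 to 65.2), Id1, an inhibitor of E protein transcription factors, 132-fold (55.9 to 411), Il2ra 6.47-fold (5.53 to 7.59), Ptcra 3.65-fold (3.39 to 3.94) and Hes1 6.82-fold (4.30 to 11.1). Hoxa7 had 130 turnover UMIs and 0 in autonomy, at most 0.0644-fold, and H1f0 370 and 3 UMIs (0.0226-fold, 0.00465 to 0.0667). Mki67, a marker of dividing cells, was at 0.848-fold (0.803 to 0.895). Notch1 was 3.17-fold higher and Il7r 1.56-fold, while Trbc1 was at 0.613-fold, Trbc2 at 0.697-fold, Dntt at 0.770-fold, Cd8b1 at 0.758-fold and Trdc at 0.536-fold. Bcl2 was 1.81-fold higher, and Myc (1.22-fold), Rag2 (1.15-fold), Rag1 (1.11-fold), Cd4 (1.05-fold), Cd3e (0.980-fold), Cd8a (0.922-fold), Bcl11b (0.859-fold) and Trac (0.844-fold) differed less. Kit had 19 and 1 UMIs (0.147, 0.00354 to 0.924) and Lyl1 2 and 3.

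Of 7957 genes in cycling cells, 553 were at least 2-fold higher and 69 lower, or 320 and 119 on TMM factors, with the median gene 0.17 higher (log2). The stricter cell filter gave 1021 genes apart and 5 times the count minimum 168. Exoc3l4 (0 and 111 UMIs, at least 103-fold), H2-T3 (3 and 143 UMIs, ratio 133, 44.6 to 653), Necab1 (2 and 98 UMIs, ratio 137, 36.9 to 1145), Arhgef10l (3 and 127 UMIs, ratio 118, 39.5 to 581) and the gamma-delta gene Cd163l1 (72.2-fold) were among the highest. Ifitm2 (1 autonomy UMI, 0.0187, 0.000471 to 0.106), Tmem238 (1 autonomy UMI, 0.0279, 0.000700 to 0.159), Gstm1 (0.148-fold) and Bmyc (0.157-fold) were among the lowest. Under the stricter filter this class held 106 autonomy cells, and an unnamed cluster of 0 turnover and 124 autonomy cells was led by Pdlim4, Cd163l1, Necab1 and Id1, with Tcrg-C4 among its leading genes. The differences of these genes were therefore not read as changes within 1 stage. Within the class Cd163l1 was then 1.72-fold higher, Hes1 3.27-fold, Cd4 2.03-fold, Mki67 1.32-fold, Cd8b1 1.15-fold, Klf2 16.4-fold, Tcrg-C4 2.199-fold, Nrarp 14.65-fold, Necab1 68.6-fold and Odc1 1.09-fold, and Il7r was at 0.821-fold and Srm at 0.587-fold, on the other side of 1, as Trbc1 (1.69-fold) and Rag2 (0.620-fold) were in cells with Y-linked transcripts only, where Ptcra was at 2.41-fold, Id1 at 80.1-fold, Cd163l1 at 139-fold, Klf2 at 90.0-fold, Socs3 at 38.1-fold, Dusp1 at 1.09-fold and Gas2l3 at 0.240-fold. With cycle scores regressed out, Il2ra was at 10.3-fold, Bcl2 at 2.87-fold, Arhgef10l at 66.6-fold and H1f0 at 0.0674-fold. Of 11 Notch genes 8 were higher and 1 lower (1.72; Nrarp 9.49-fold), of 14 interferon genes 13 higher (1.48; Ifi27l2a 8.33-fold, Usp18 5.80-fold), and of 9 gamma-delta genes 6 higher and 1 lower (1.202; Tcrg-C4 5.56-fold). MHC class I genes (8 of 11 higher and 1 lower, 0.67; H2-D1 2.46-fold, H2-Q4 2.32-fold), interleukin-7 receptor and STAT5 genes (8 of 13, 0.51; Socs3 58.6-fold, Socs1 3.17-fold) and T commitment genes (7 of 14, 0.50; Tcf3 3.78-fold, Runx3 2.19-fold) were higher. Glucocorticoid (5 of 9, 0.45; Fkbp5 2.47-fold, Dusp1 1.69-fold), quiescence (7 of 13, 0.43; Klf2 33.0-fold, Foxo1 6.73-fold) and TCR response (6 of 13 higher and 2 lower, 0.41; Dusp5 4.13-fold, Dusp2 2.96-fold) genes were higher by their medians. For MYC-linked ribosome genes the median stood above random lists (0.25), but 2 of 15 members were at least 1.5-fold higher (Odc1 1.93-fold, Srm 1.59-fold), and neither was under the stricter filter. For G2/M genes the median stood below random lists (-0.19), but 3 of 52 members were at least 1.5-fold lower and 1 higher (Gas2l3 0.592-fold, Tmpo 1.63-fold). For ribosomal protein genes it stood below them as well (-0.27), with 1 of 20 members at least 1.5-fold lower (Rps12 0.636-fold, Rpl23 0.713-fold), and the sex check list stood at -1.95. For V(D)J recombination the median also stood below random lists (-0.25), but 2 of 12 members were at least 1.5-fold higher and none lower (Xrcc6 2.66-fold, Lig4 0.756-fold).

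In post-selection-like cells, which have received a TCR signal, Dtx1 had 1 turnover and 136 autonomy UMIs (ratio 112, 19.8 to 4467). At 72.6 CPM this was its lowest level among the autonomy classes compared, and free Dtx1 RNA was not excluded as the source of all of it. Myc, a driver of growth, was 7.35-fold higher (5.03 to 11.1), Ptcra 8.46-fold (4.10 to 20.3), Il2ra 6.77-fold (3.50 to 14.7), Notch1 3.64-fold (2.27 to 6.08) and the survival gene Bcl2 2.03-fold (1.70 to 2.42). Hdgfl3 was 19.3-fold higher, Ifi27l2a 14.2-fold, Rtp4 8.52-fold and Igf2bp3 8.34-fold. H1f0 (0.265-fold), Nrgn (0.312-fold), Tpi1 (0.371-fold), Lgals1 (0.3799-fold), Mgst3 (0.392-fold) and Trbc1 (0.400-fold) were lowest, and Dntt (0.527-fold), Cd8b1 (0.582-fold), Cd8a (0.684-fold), Trbc2 (0.525-fold) and Trdc (0.172-fold) were lower. Cd4 (1.04-fold), Bcl11b (0.929-fold), Cd3e (0.827-fold) and Trac (0.773-fold) differed little, Lyl1 had 2 and 14 UMIs (ratio 5.78, 1.33 to 52.4), Mki67 10 and 7 (0.578-fold), Hes1 0 and 1, and Kit 0 and 5, too few for a direction. Rag1 (0.792-fold) and Rag2 (0.755-fold) were at 2.81-fold and 1.77-fold under the stricter filter. Trdc was at 0.392-fold with cycle scores regressed out and 0.0916-fold without centring. Under 6 other settings Dtx1 lay between 44.8-fold and 69.3-fold, and Ptcra was at 2.55-fold with the highest doublet scores removed and 15.7-fold at a resolution of 0.5. With the looser filter Il2ra was at 4.32-fold, Hdgfl3 at 11.9-fold, Rtp4 at 4.71-fold and H2-K1 at 1.93-fold, and Myc was at 4.61-fold with cycle scores regressed out. Il7r was 3.30-fold higher from 7 and 28 UMIs, but lower under 4 other settings, at 0.807, 0.728, 0.844 and 0.412, and Ccr7 (1.91-fold) was at 0.824-fold when libraries were not centred. In cells with Y-linked transcripts only, Hdgfl3 was at 41.1-fold, Il7r at 6.85-fold, Ccr7 at 5.96-fold and Odc1 at 2.17-fold.

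Of 5164 genes in these cells, 318 were at least 2-fold higher and 29 lower, or 250 and 48 on TMM factors, and the median gene stood 0.08 higher (log2). With 5 times the count minimum 51 genes were apart, and with a lower minimum 632. Of 7 Notch genes 5 were higher and 1 lower (2.55), and all 14 interferon genes were higher (1.85). Interleukin-7 receptor and STAT5 (8 of 12, 0.92; Pim1 2.79-fold, Socs1 2.53-fold), MYC-linked ribosome (8 of 15, 0.56; Srm 3.67-fold, Odc1 3.50-fold), immediate early (5 of 11, 0.57; Jund 3.44-fold, Ier2 2.06-fold), MHC class I (4 of 10, 0.53; H2-K1 3.099-fold, H2-D1 2.62-fold) and innate genes (3 of 6 higher and 1 lower, 0.60; Xcl1 3.17-fold, Cd160 2.13-fold) were higher by their medians. Mature thymocyte (5 of 13, 0.47; Gimap4 2.56-fold), quiescence (5 of 12 higher and 1 lower, 0.47; Foxo1 4.06-fold, Btg1 2.61-fold), T commitment (5 of 14, 0.44; Tcf3 4.26-fold, Gata3 1.67-fold), TCR response (5 of 15, 0.39; Dusp5 3.72-fold, Dusp2 2.89-fold), p53 (5 of 12, 0.39; Bax 1.86-fold, Fas 0.678-fold) and chromatin genes (6 of 18 higher and 1 lower, 0.30; Hdac7 2.03-fold, Hdac2 1.71-fold) were higher in the same way. Medians stood below random lists for V(D)J recombination (4 of 12 lower, -0.49; Hmgb2 0.519-fold), hypoxia (4 of 10 lower and 2 higher, -0.48; P4ha1 0.617-fold, Ero1l 1.61-fold), DP stage (3 of 15 lower and 1 higher, -0.19; Ets2 1.99-fold) and B cell genes (2 of 4 lower, -0.71; Ighm 0.732-fold), and the sex check list stood at -1.90.

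**Figure D1:**
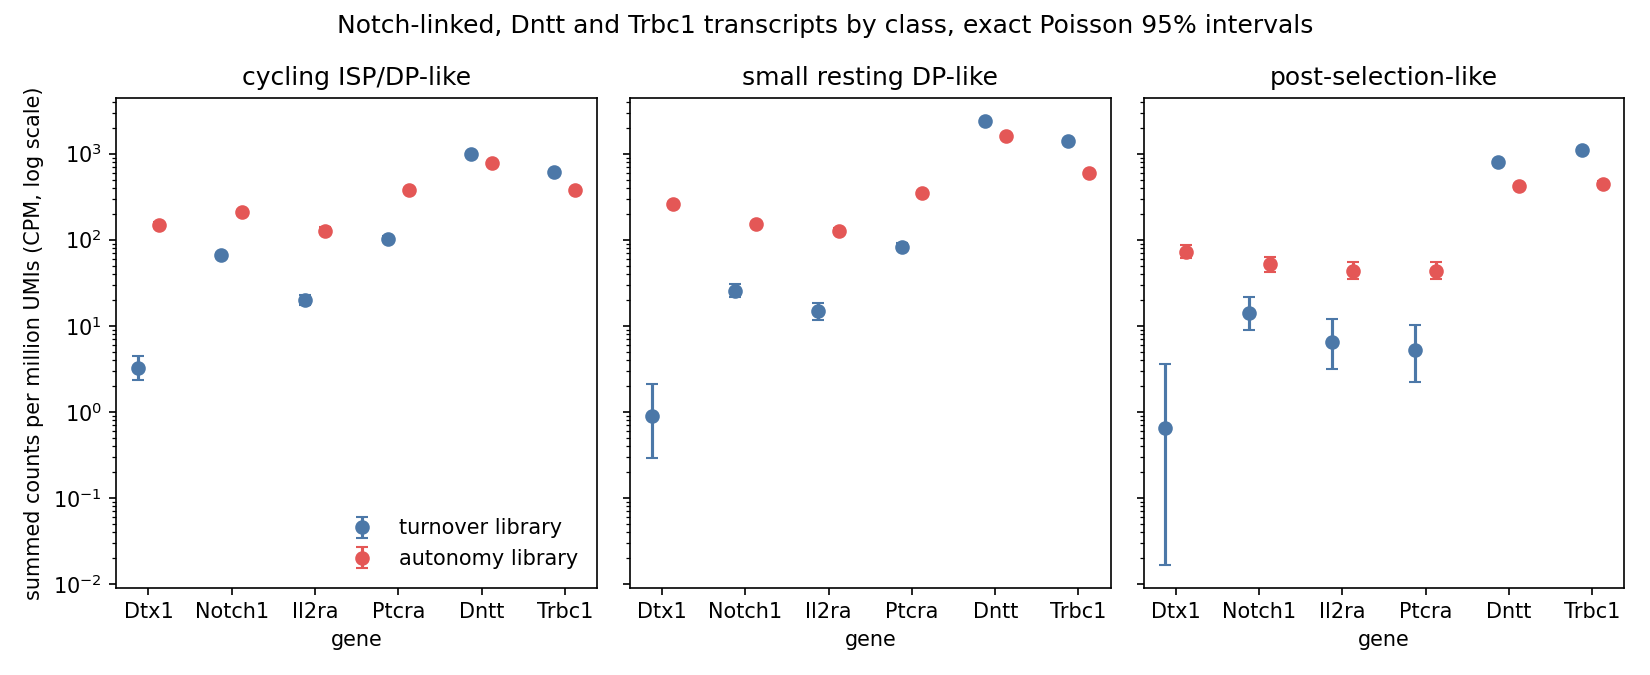
CPM of Dtx1, Notch1, Il2ra, Ptcra, Dntt and Trbc1 on a log axis in the summed cells of each class, with exact Poisson 95% intervals, for the turnover and the autonomy library. In small resting cells Dtx1 stood at 0.901 in turnover and 258 in autonomy, and Trbc1 at 1414 and 600.2.

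Cell cycle phase was scored per cell after thinning each cell to 1000 UMIs. S or G2/M calls covered 24.0% of turnover cells (22.8 to 25.4) and 15.7% of autonomy cells (14.6 to 16.8), a ratio of 0.651, and without thinning 21.3% and 10.0%. Within cycling cells they covered 97.3% and 93.8% (98.2% and 94.1% without thinning), and within small resting cells 9.64% and 10.5% (6.39% and 4.62%), where Mki67 was at 3.61 and 1.87 CPM. The share in small resting cells was therefore not read as division. The ratio over all cells moved between 0.470 without thinning and 0.747 with the highest doublet scores removed.

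A productive beta chain (TRB) is needed to pass beta-selection, and its share by stage was the next comparison. Among cycling cells, 95.1% of turnover cells (93.2 to 96.6) and 62.9% of autonomy cells (56.7 to 68.8) carried a productive TRB chain, a ratio of 0.661 (0.601 to 0.728). Among small resting cells the shares were 89.9% (88.7 to 91.0) and 78.5% (76.8 to 80.1), and among post-selection-like cells 90.8% (88.1 to 93.0) and 92.4% (89.7 to 94.5). In the Il2ra-high cluster, where few cells should have completed the rearrangement, 15.6% of 122 turnover cells (9.65 to 23.3) and 0 of 8 autonomy cells (up to 36.9) carried one. Median gene expression depth there was 8068 and 7798 UMIs, against 15572 and 14151 in cycling cells, and TRB-bearing cycling cells held a median of 70 TRB UMIs in turnover and 22 in autonomy. Over all kept cells the shares were 88.5% and 72.9%.

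**Figure D2:**
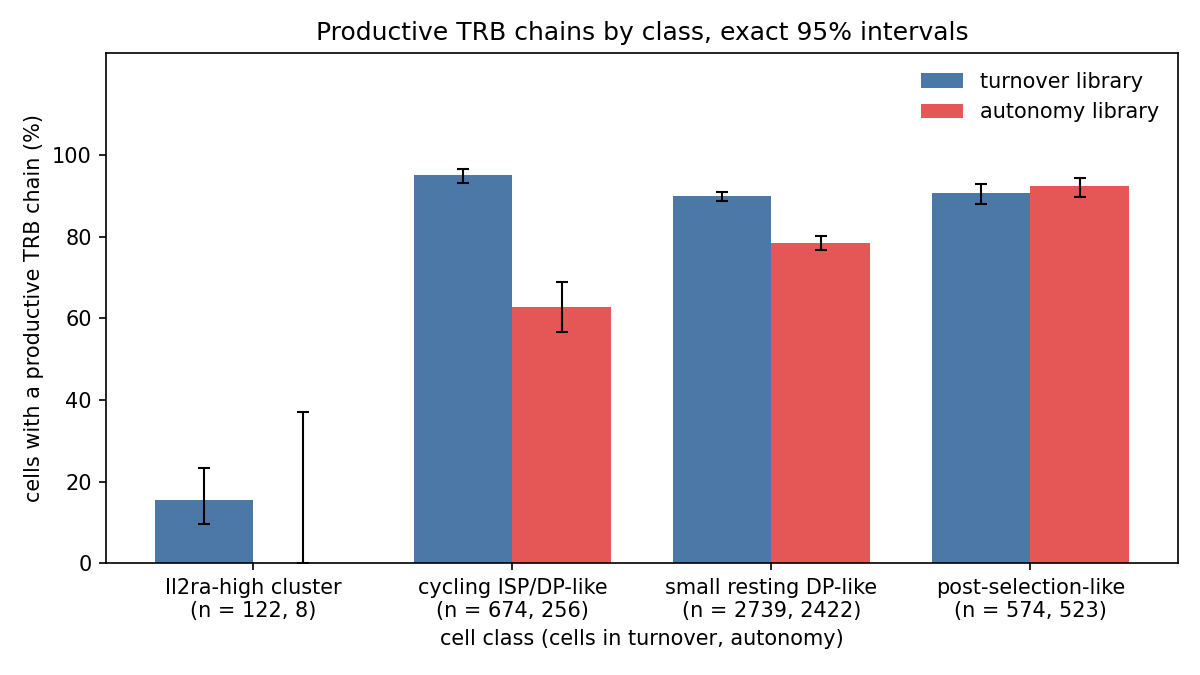
Percentage of cells with at least 1 productive TRB contig, with exact 95% intervals, in the Il2ra-high cluster and 3 classes of each library. Cycling cells stood at 95.1% in turnover and 62.9% in autonomy, and post-selection-like cells at 90.8% and 92.4%.

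Among cycling and small resting cells together, 9.08% of turnover cells (8.14 to 10.1) and 23.0% of autonomy cells (21.5 to 24.7) had no productive TRB chain, a ratio of 2.54 (2.24 to 2.88). Among those that carried a productive alpha chain (TRA), 8.14% and 19.2% had none. Of cells with any TRB contig, 10.7% in turnover and 23.2% in autonomy held only unproductive ones, and of all cycling cells 1.93% and 28.1% held only unproductive contigs with V and J. The Dtx1-led clusters carried a productive TRB chain in 78.7% and 48.2% of cells. Productive TRA chains were found in 41.7% of turnover (40.2 to 43.2) and 42.4% of autonomy cells (40.9 to 43.8), a ratio of 1.02. By class they were found in 42.1% and 39.5% of small resting cells, 9.50% and 7.81% of cycling cells, 85.2% and 85.3% of post-selection-like cells and 3.28% of the turnover Il2ra-high cluster. Counting any contig with V and J brought the TRB ratio in cycling cells to 0.938.

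Sharing of a chain between cells can come from clones that divided after the rearrangement, but does not show this by itself. A chain of TRBV12-2 and TRBJ2-7 was carried by 51 autonomy cells and 1 turnover cell. Of these autonomy cells, 10 had Xist and no Y-linked transcripts and 20 had Y-linked transcripts alone, so it need not come from 1 clone. In turnover, 3982 productive TRB chains held 3899 distinct nucleotide chains, and in autonomy 3524 chains held 827. Of these chains, called productive in the deposited tables, 0.779% in turnover and 7.21% in autonomy had V and J out of frame with each other. At equal cell numbers, 3.50% of turnover and 85.0% of autonomy TRB-bearing cells shared their TRB chain with another cell (4.26% and 85.4% over all cells). The largest autonomy chains were carried by 191, 185 and 143 cells, and those of 191 and 185 cells were found together in 174 cells. The chains of TRBV13-1 with TRBJ2-4 in 58 cells and with TRBJ1-5 in 45 cells were out of frame. In autonomy, 69 chains in at least 10 cells each made up 60.4% of its TRB chains. No turnover chain was found in more than 3 cells. Sharing in autonomy was 83.9% in cycling, 88.4% in small resting and 85.3% in post-selection-like cells, against 12.2%, 2.68% and 2.11% in turnover. Mature single positive-like cells stood apart, with 18.5% of 135 autonomy cells sharing (12.4 to 26.1) and 0 of 16 turnover cells (up to 20.6). TRA chains, which rearrange later, were shared by 0.687% and 0.967% of TRA-bearing cells. Only 1 TRB and 15 TRA chains were found in both libraries.

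**Figure D3:**
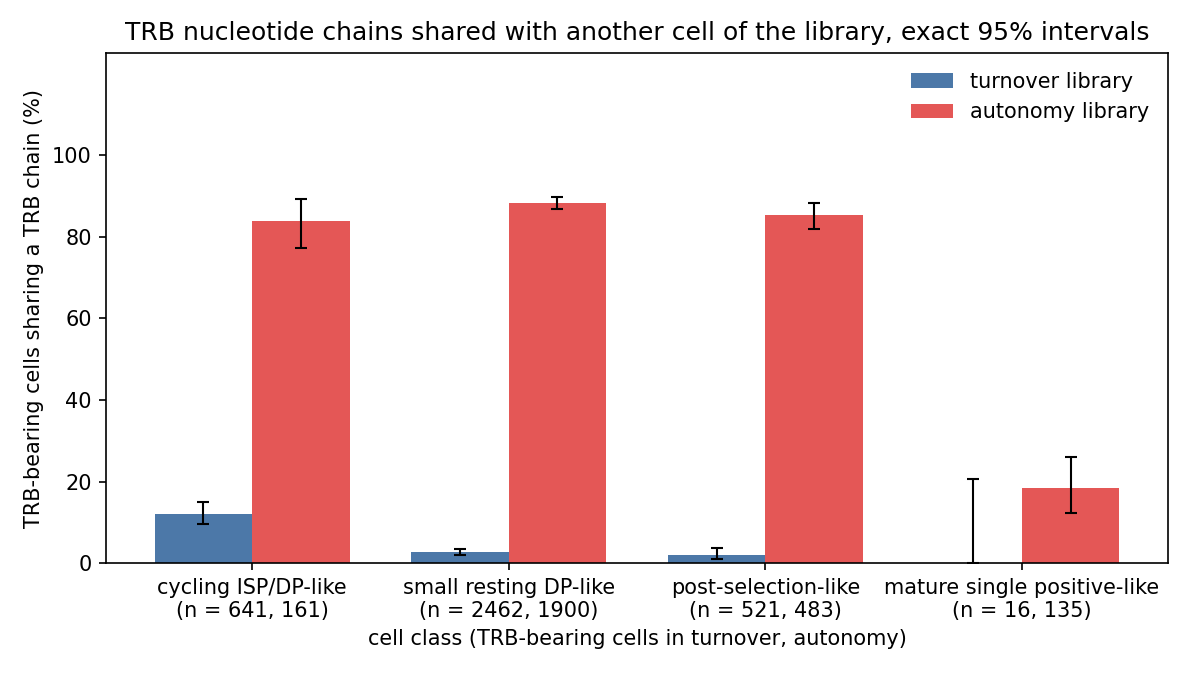
Percentage of TRB-bearing cells that shared their nucleotide TRB chain with another cell of the same library, with exact 95% intervals, in 4 classes. Autonomy small resting cells stood at 88.4% and mature single positive-like cells at 18.5%.

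Segment usage differed most for TRBJ. The TRBJ2 cluster, which lies downstream of TRBJ1, was used by 61.3% of turnover chains (59.8 to 62.8) and 88.7% of autonomy chains (87.6 to 89.8), or by 86.1% of autonomy chains when each distinct chain counted once. TRBJ2-4 was used by 8.94% and 21.8%, TRBJ2-5 by 13.4% and 23.4% and TRBJ2-2 by 6.08% and 9.08%, while TRBJ1-6 was used by 3.37% and 0.170%, TRBJ1-2 by 6.33% and 0.880% and TRBJ1-3 by 6.08% and 1.11%. Over distinct chains, TRBJ2-2 was equal at 6.16% and 6.17%, and the ratio was 1.67 for TRBJ2-4, 0.143 for TRBJ1-6, 0.256 for TRBJ1-3 and 0.399 for TRBJ1-2. The Jensen-Shannon divergence between libraries was 0.107 bits for TRBJ and 0.0375 for TRBV, above the highest of 100 random splits within a library (0.00541 and 0.00881). Over distinct chains TRBJ stood at 0.0767, above its splits (up to 0.0261), and TRBV at 0.0320, below the highest split of autonomy (0.0391) and above that of turnover (0.00731). These splits hold fewer chains and so diverge more by chance, and for TRBV no call was made. Over all chains, TRBV29 (2.99% and 6.24%), TRBV13-1 (6.78% and 11.3%) and TRBV31 (3.89% and 5.51%) were higher in autonomy and TRBV20 (4.27% and 1.39%), TRBV17 (2.66% and 1.02%) and TRBV23 (0.829% and 0.369%) lower. Over distinct chains the ratios of TRBV29 (2.87% and 2.54%), TRBV13-1 (1.09), TRBV20 (0.898), TRBV17 (0.824) and TRBV23 (0.760) had intervals that included 1. For these segments no difference was called where each distinct chain counted once. TRBV31 (1.43, 1.04 to 1.97), TRBV24 (0.564% and 1.69%) and TRBV13-3 (4.51% and 14.3%) were higher over distinct chains, and TRBV12-1 (0.536, 0.368 to 0.782) and TRBV4 (0.589, 0.404 to 0.861) were lower.

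For TRA, the divergence was 0.0231 bits for TRAV and 0.0228 for TRAJ, and the splits, which hold fewer chains and so diverge more by chance, were no measure of values this small. Upstream TRAJ segments, numbered 40 or higher and used in early alpha rearrangements, made up 26.2% of turnover (24.2 to 28.2) and 16.6% of autonomy chains (14.97 to 18.2). TRAJ57 (1.74% and 0.730%), TRAJ56 (2.26% and 0.974%) and TRAJ58 (1.54% and 0.682%) were lower in autonomy, and TRAJ2 (2.26% and 4.09%) and TRAJ16 (1.28% and 2.48%) higher. For TRAJ24 (13 and 26 chains, ratio 1.90, 0.979 to 3.69) the interval included 1. TRAV9N-2 (ratio 0.475), TRAV21/DV12 (0.508) and TRAV3-3 (0.590) were lower and TRAV1 (1.75), TRAV9-1 (2.01) and TRAV14-3 (2.38) higher. The mean TRB CDR3 length was 14.26 amino acids in turnover (SD over chains 1.56) and 14.81 in autonomy (SD 2.08), but over distinct chains 14.26 and 14.29, and for TRA 13.76 and 13.78.

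**Figure D4:**
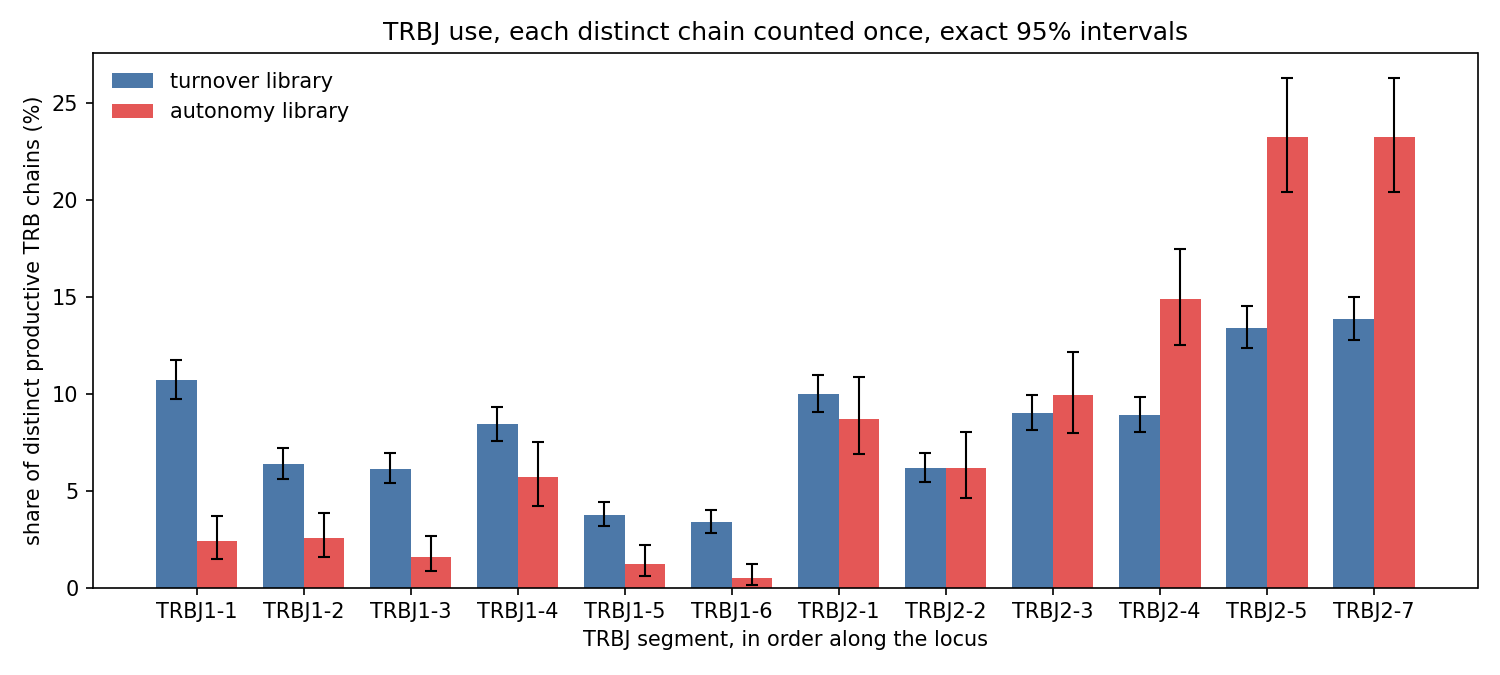
Percentage of distinct productive TRB chains that used each TRBJ segment, with exact 95% intervals, for the turnover and the autonomy library. TRBJ2-5 stood at 13.4% and 23.2%, and TRBJ1-1 at 10.7% and 2.42%.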

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

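No tests were run on the 3 values given first, which were looked for only after the data had been seen. In the autonomy library 1773 cells carried Xist and no Y-linked transcripts, 931 carried Y-linked transcripts alone and 25 both, while no turnover cell had a Xist UMI. An unproductive TRB chain of TRBV4 and TRBJ2-3 was carried by 180 autonomy cells, and no unproductive turnover chain by more than 1. The macrophage-transcript cluster held 140 autonomy and 17 turnover cells, with Lyz2 at 1090 CPM beside Cd8a at 2752 CPM, and 66.4% of its autonomy cells had a productive TRB chain.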

How the results depend on the processing

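No paired analysis was possible because each condition had 1 library. Alternatives with libraries not centred, the highest Scrublet scores removed, genes 4-fold apart left out, V and J in frame, Dtx1-led clusters added, Y-linked transcripts only, or mature and macrophage-transcript clusters left out, and TRBJ2 over distinct chains, were chosen after the data were seen. Of 188 alternative values of the comparisons 143 stayed close to the first value, 45 moved and 0 reversed. The 143 include values with called doublets kept, which repeat the first value because no doublet was called. Counting the Dtx1-led clusters as small resting cells, which would turn the direction of that share, was not among the 188. Of 413 values for gene groups 394 stayed close, 19 moved and 0 reversed. Of 2787 gene folds 2169 stayed close, 609 moved and 9 reversed. A value was close when it lay inside the 95% interval of the first value (for gene groups, the median interval of the members), a gene count when it lay within 1.5 times the first, and a divergence when it moved by no more than the highest random split. Gene folds were called reversed only where at least 1.5-fold from 1 at first. Folds nearer to 1 also crossed it, such as Il7r over all cells (1.38-fold), at 0.864-fold with cells thinned. For each value below that moved or reversed, the cause was not tested.

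The ratio of small resting shares (0.843) was 0.908 with the looser filter, 0.788 with the stricter one, 0.997 at a resolution of 0.5, 0.890 with cycle scores regressed out, 0.781 without centring and 0.983 with genes 4-fold apart left out. The phase ratio (0.651) was 0.729 with the looser and 0.597 with the stricter filter, 0.470 without thinning and 0.747 with the highest Scrublet scores removed.

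The productive TRB ratio over all cells (0.823) was 0.846 with the stricter filter, 0.858 among cells with any contig, 0.956 for any contig with V and J, 0.771 in frame and 0.859 in cells with Y-linked transcripts only. In small resting cells (0.873) it was 0.904 with the stricter filter, 0.832 at a resolution of 0.5, 0.899 without centring, 0.899 among cells with any contig, 0.958 with V and J, 0.839 in frame and 0.910 with Y-linked transcripts only. In cycling cells (0.661) it was 0.938 with V and J, 0.534 in frame and 0.742 with Y-linked transcripts only. The ratio of cells without a productive TRB chain (2.54) was 1.90 with V and J, 2.90 in frame and 3.27 with Dtx1-led clusters added. The TRA ratio was 1.15 with the stricter filter, and that of only unproductive TRB contigs (2.17) was 2.58 in frame.

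The ratio of chain sharing (24.3) was 18.0 by amino acid CDR3, 20.1 over all cells and 61.4 with Y-linked transcripts only. Over distinct chains the TRBJ divergence was 0.0767, the TRBJ2 ratio 1.41 and the difference in TRB CDR3 length 0.0271 (0.544 over all chains).

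Genes at least 2-fold apart over all cells (1432) were 649 with 5 times the minimum and 507 with cells thinned. In small resting cells (733) they were 261 with 5 times the minimum and 479 with Y-linked transcripts only, in cycling cells (622) 168 with 5 times the minimum and 1021 with the stricter filter, and in post-selection-like cells (347) 632 with 0.5 times the minimum, 51 with 5 times and 113 with Y-linked transcripts only. With Y-linked transcripts only, Trbc1 was at 1.05-fold over all cells and 1.69-fold in cycling cells. With the stricter filter, Il7r was at 0.821-fold and Srm at 0.587-fold in cycling cells. In post-selection-like cells Ccr7 was at 0.824-fold without centring, and Il7r at 0.807-fold with the looser filter, 0.728-fold with no gene left out of the variable genes, 0.844-fold with cycle scores regressed out and 0.412-fold without centring. For 25 gene folds an alternative left a library at 0 UMIs and gave no value. Keeping called doublets could change nothing, since none was called, and alternatives for genes of DN3-like cells were not run.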

Other observations

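Of the tests given here, those on V(D)J recovery, on free TRB RNA, on 1 sex for TRB, on Dtx1 at a like number of UMIs and as the source of the whole level, on free V(D)J RNA, on the number of animals and on expanded clones for TRBJ2 were chosen only after the result was seen, and the others beforehand.

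Among autonomy cycling cells, the 95 without a productive TRB chain had 2.49-fold more Ptcra (2.25 to 2.75), 2.19-fold more Il2ra and 2.82-fold more Id1 than the 161 with such a chain. Mki67 (1.07-fold) and Trbc2 (0.993-fold) were near equal, and Trbc1 was at 0.160-fold. Higher Il2ra and Ptcra were not particular to autonomy. In turnover, the 33 cycling cells without such a chain had 13.8-fold more Il2ra (10.4 to 18.2) and 1.76-fold more Ptcra (1.39 to 2.20) than the 641 with one. Trbc1 was at 1.18-fold there, and Id1 had 1 and 4 UMIs. A pair of productive chains, TRBV13-2 with TRBJ2-4 and TRBV29 with TRBJ2-5, was found together in 174 autonomy cells, of which 110 lay in the Dtx1-led cluster of Lypd1, among its 154 autonomy cells, and none of the 70 with a TRA chain shared it.

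Fewer autonomy cells among cycling and small resting cells carried a productive TRB chain. Lower V(D)J recovery in all classes would have lowered post-selection-like cells too, but the lower bound of their ratio was 0.982, which argued against it. This cannot exclude lower recovery in cycling or small resting cells alone. No TRB contig at all was found in 0.762% of turnover and 4.07% of autonomy cycling and small resting cells. Among post-selection-like cells the shares were 0.348% and 1.34% (2 and 7 cells). Cells without a contig count among those without a productive chain. Median TRB UMIs of TRB-bearing cycling cells were 70 in turnover and 22 in autonomy, but 21 and 18 in post-selection-like cells. Free TRB RNA or doublets in turnover would have marked the Il2ra-high cluster, where the upper bound was 23.3%, against 95.1% in cycling cells. Cells of 1 sex did not carry the result, since the upper bound in cells with Xist or with Y-linked transcripts stayed at 84.2% or lower. Clones were not tested as a source. Of the 617 autonomy cells without a productive TRB chain, 242 carried an unproductive chain with a CDR3. These held 92 distinct chains, and 1 chain was found in 84 cells. In turnover, 92 of 310 such cells held 93 distinct chains, none of them in more than 1 cell. The condition itself and other differences between the libraries stay open, as untested.

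Dtx1 was far higher in small resting autonomy cells. Large TRB clones and cells of 1 sex were argued against by lower bounds of 128-fold without the large clones and 119-fold within either sex group. Free Dtx1 RNA in proportion to the UMIs of each droplet was argued against as the source of the whole level. Dtx1 stood at 258 CPM in small resting, 149 in cycling and 72.6 in post-selection-like autonomy cells. The lower bound was 2.99 for small resting over post-selection-like cells, where the level itself was not tested. The 595 CPM of the Dtx1-led clusters was not counted, since Dtx1 was among the genes that set them apart. As a source of part of the level, free Dtx1 RNA cannot be told apart from expression. The CPM ratio over mature single positive-like cells, the test chosen beforehand, was 1.92 (1.67 to 2.23), on both sides of 2. Free Dtx1 RNA at a like number of UMIs in every droplet was argued against, with a lower bound of 2.03 for the ratio of UMIs per cell over post-selection-like cells.

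Most autonomy cells with a TRB chain shared it. Free V(D)J RNA or barcode errors that spread the chains of single cells would have spread TRA chains as well. In cells of chains carried by 10 or more cells the upper bound of TRA sharing was 1.22%, which argued against this. Free TRB RNA of a chain carried by many cells cannot be excluded this way, since 2036 of 2044 distinct autonomy TRA chains were seen once. A few very large clones did not carry the result, since 80.8% of the remaining cells shared a chain without the 10 largest. The number of animals or progenitors behind each library cannot be told apart from the condition, with 1 library per condition.

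For the higher TRBJ2 share in autonomy, a few expanded clones were argued against by a lower bound of 83.6% over distinct chains, and selection on the protein by 82.7% among distinct unproductive chains (58.3% in turnover). For autonomy cycling cells without a productive TRB chain, gamma-delta lineage cells were argued against by a Trdc ratio of 0.390 (0.274 to 0.544) against cells with such a chain.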
